A study of Mus musculus with 12 samples.

How the data were processed

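Gene expression was measured by mRNA sequencing in 12 heart samples of mice aged 6 months, 3 samples in each of 4 groups. Per the labels' protocols, mRNA was enriched with oligo(dT) beads and sequenced on DNA nanoballs. The groups were nontransgenic mice, mice homozygous for a 25 bp deletion in MYBPC3, mice heterozygous for the HRC variant S96A, and compound mice that carry both alterations. Per the labels, the nontransgenic group and the MYBPC3 deletion group each held 2 males and 1 female, while all HRC variant mice and all compound mice were female. The replicates are separate mice only as far as the labels say, so p-values measure the spread between these samples.

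The authors deposited one table with an expected count per gene and sample, that is, an estimated number of reads that need not be whole. Of the count values in the deposited table, 94.3% were whole numbers, with no tolerance for rounding. The same deposited table gives the authors' log2 fold changes and DESeq2 q-values for pairs of groups, per the file headers. The submitters' processing notes name HISAT, Bowtie2, DESeq2 and the genome build GRCm38.p6. The role and version of each tool, the counting tool and the annotation are not given in the sources used here. The table had 17380 lines after its header, of which 1 held no values and was dropped, which left 17379 genes. A spreadsheet had turned 25 symbols into dates, and these were restored from the gene identifiers. Xist and the genes encoded in mitochondrial DNA were not analysed here. Coordinates were taken from the deposited table. A RefSeq gene table of the same build, in which 17267 identifiers matched, served to restore the symbols and to check chromosomes, which agreed in 100%.

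Counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Total counts ranged from 15615182 to 20581197 per sample. Genes were kept by edgeR's filter on low counts, with a minimum count of 10, which left 13849 genes and removed 3530. Libraries were scaled by trimmed mean of M values (TMM). One quasi-likelihood model (robust, in this version's default legacy form) was fitted over all 12 samples with group and sex as terms, which left 7 residual degrees of freedom, and the common biological coefficient of variation was 21.5%. Sex was estimated within the groups that held both sexes. The contrasts were each mutant group against nontransgenic mice, the compound group against each single mutant, and the interaction, which is the compound difference less the sum of the single differences on the log2 scale. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Throughout, an adjusted p without another tool's name is that of edgeR's quasi-likelihood test for a gene, and of camera for a gene list or term.

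Before the data were examined, 44 gene lists were fixed for heart muscle functions and for markers of other cell types, together with the contrasts, the covariate, most alternative settings and the rule for named genes. The 40 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes. Each was tested again with the correlation estimated from the data, and with fry. KEGG and GO terms of the deposited table with 10 to 300 tested genes were tested in the same way. The rule named Mybpc3 and Hrc first, then the 8 higher and 8 lower genes with the largest change among called genes (mean log2 CPM of at least 1, without model or clone names and sex-linked genes), the 5 genes with the smallest p where fewer than 10 were called, up to 4 members with the smallest p of each list that passed, and a fixed set of heart failure markers in the comparisons with nontransgenic mice. A further gene that the rule names is not reported here. Since edgeR called no gene, the genes named by it are given with values, and counted as higher or lower members of a list only by sign. Genes that share reads with a close copy are uncertain, since the counting rule is not given in the sources used here. All values of 10 genes were identical to those of another gene. H2 genes, B-cell genes and predicted genes of repeated families belong among the uncertain ones.

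The test was checked on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the MYBPC3 deletion against nontransgenic mice, edgeR recovered 55% of the 2-fold and 88% of the 4-fold changes, with 8 unchanged genes called, among 13687 genes. For the HRC variant against nontransgenic mice it recovered 40% and 86%, with 5 unchanged genes called, among 13695. For the compound group against nontransgenic mice the shares were 44% and 85%, with 11 unchanged genes called, among 13693. For the interaction they were 30% and 78%, with 4 unchanged genes called, among 13693. DESeq2 1.42.0 recovered 61% and 91%, 54% and 90%, 60% and 89%, and 43% and 86% in the same order, and called 34, 28, 38 and 23 unchanged genes.

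Alternatives covered the sex term, DESeq2, limma-voom, the edgeR likelihood ratio test, size factors of DESeq2 (RLE), filters on low counts, the samples in the fit, the replicate number as a block, leaving out each library in turn, and the genes on X and Y. Some were chosen after seeing the data, among them a model with the mean log2 CPM of Myl7, Myl4 and Sln per library, called the atrial level here, and a model with each library's trend on transcript length removed. Transcript length, that of the longest protein-coding transcript in GENCODE vM21, was known for 13604 of the tested genes (98.2%). CPM values are counts scaled to TMM-adjusted library sizes. Replicates of a group differed by 10.5 to 80.3 in chi-square per degree of freedom, so no library was taken to have been deposited more than once. Fold changes are relative to the bulk of genes, whose median lay within 0.03 of 0 in each contrast under TMM, RLE and the length correction.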

Results

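The data were 12 libraries of mouse heart mRNA, 3 per group. HRC encodes a histidine-rich calcium-binding protein of the sarcoplasmic reticulum, and MYBPC3 encodes cardiac myosin-binding protein C of the thick filament. Total counts were 18862067, 18756365 and 20581197 in the nontransgenic libraries, 15615182, 16161206 and 17999983 with the MYBPC3 deletion, 19380628, 18392002 and 18515905 with the HRC variant, and 18108213, 17796067 and 18077980 in the compound libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty followed the sex labels: Ddx3y had 798 to 1268 reads in the 4 male libraries and 0 to 8 in the 8 female ones.

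The altered genes were both transcribed in every group. Mybpc3 (gene 17868; GRCm38.p6 chromosome 2, 91118022 to 91136573, plus strand) had 4010 ± 758 CPM (SD, n = 3) in nontransgenic hearts, with 4890, 3520 and 3630 in the single libraries. It had 2640 ± 245 CPM with the MYBPC3 deletion (2460, 2920 and 2530), 3350 ± 478 with the HRC variant (2900, 3300 and 3850) and 3700 ± 200 in compound hearts (3530, 3660 and 3920). The fitted log2 difference of Mybpc3 between the deletion and nontransgenic hearts was -0.60 (SE 0.16), with an edgeR adjusted p of 0.357 and a DESeq2 adjusted p of 0.0188. Between compound hearts and the MYBPC3 deletion alone it was 0.59 (SE 0.20; adjusted p = 0.862). Hrc (gene 15464; GRCm38.p6 chromosome 7, 45335269 to 45338973, plus strand) had 1130 ± 224 CPM in nontransgenic hearts (1380, 939 and 1070), 1080 ± 112 with the MYBPC3 deletion (1200, 974 and 1070), 1160 ± 190 with the HRC variant (956, 1200 and 1330) and 1180 ± 38.8 in compound hearts (1160, 1170 and 1230). Its log2 difference was 0.08 (SE 0.21) between the HRC variant and nontransgenic hearts, less than the spread between replicates. A short deletion and a single-residue variant leave a transcript that is still counted, so these counts do not check the genotype labels.

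**Figure D1:**
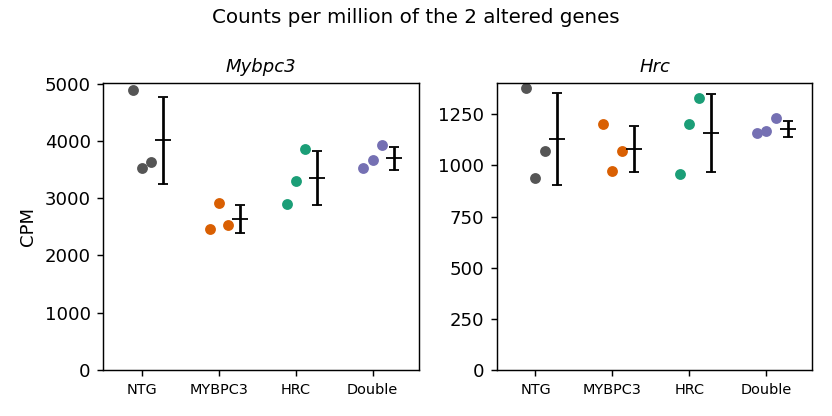
CPM (vertical axis, from 0) of Mybpc3 and Hrc in each library, by group. Points are libraries and the black mark with bars is the mean ± SD (n = 3). Mybpc3 lay between 2460 and 2920 CPM with the MYBPC3 deletion and between 3520 and 4890 CPM in nontransgenic hearts.

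The first comparison asked how hearts with the homozygous MYBPC3 deletion differ from nontransgenic hearts. The sarcomere list fell, with a median log2 fold change of -0.19 (quartiles -0.35 and 0.01) and 22 of 30 members lower, among them Flnc, which crosslinks actin at the Z-disc (-0.71, SE 0.13), and Myh6, the adult alpha myosin heavy chain (-0.53, SE 0.15). No member passed edgeR over all genes, and 3, Myh6, Mybpc3 and Flnc, passed adjusted over the list alone and DESeq2 over all genes (camera adjusted p = 0.00157, but adjusted p = 0.898 with an estimated correlation). The cell cycle list rose by a median of 0.43, with 27 of 30 members higher and 0 passing edgeR or DESeq2 over all genes or adjusted over the list alone. Its adjusted p was 1.5e-05, but 0.898 with an estimated correlation. Its members included Ccnb2, a mitotic cyclin (2.05, SE 0.53), and Cdk1, the kinase it activates (1.07, SE 0.49). Relative to the mean of all libraries the list lay at 0.77 in MYBPC3 deletion replicate 2 and 0.36 in nontransgenic replicate 2, the libraries where B-cell markers lay at 3.01 and 2.52 and T-cell markers at 0.87 and 0.63. The list of glycolysis and glucose use fell, with a median of -0.19 and 27 of 30 members lower, among them Pfkl, a phosphofructokinase subunit (-0.51, SE 0.14), the 1 member that passed DESeq2. The list's adjusted p was 0.000832, but 0.898 with an estimated correlation. The 5 genes with the smallest p were Flt1, a receptor for vascular endothelial growth factor (gene 14254; GRCm38.p6 chromosome 5, 147561606 to 147726005; -0.96, SE 0.15), Xdh, which makes uric acid (-0.81, SE 0.13), Htt, which encodes huntingtin (-0.81, SE 0.14), Ubr4, a ubiquitin ligase (-0.61, SE 0.11), and Flnc.

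Another 8 lists passed camera in the comparison of the MYBPC3 deletion with nontransgenic hearts. Lower were heat shock proteins (median -0.21, 19 of 21 lower, adjusted p = 0.00752), hypoxia and angiogenesis (-0.19, 22 of 28 lower, adjusted p = 0.00752) and endothelial markers (-0.10, 11 of 18 lower, adjusted p = 0.0197), with 0.898, 0.306 and 0.898 by an estimated correlation. Higher were macrophage markers (0.27, 18 of 22, adjusted p = 0.0112), extracellular matrix (0.16, 35 of 46, adjusted p = 0.0112), antigen presentation (0.31, 17 of 19, adjusted p = 0.0165), ribosomal proteins (0.10, 34 of 37, adjusted p = 0.018) and the interferon response (0.15, 26 of 34, adjusted p = 0.0439). With an estimated correlation the adjusted p was 0.898 for each of these 5. Over all genes 0 members passed edgeR, while DESeq2 called Flt1 (both lists) and Epas1 (hypoxia), and adjusted over the list alone 1 passed in the hypoxia and endothelial lists, Flt1 in both. Hsph1, a heat shock chaperone, gave -0.84 (SE 0.25), Kdr, the main endothelial growth factor receptor, -0.49 (SE 0.17), Fcgr1, an antibody receptor of macrophages, 1.09 (SE 0.43), and Eln, the elastin gene, 0.74 (SE 0.28). Of the markers of heart failure, the natriuretic peptide genes Nppa (-0.36, SE 0.96) and Nppb (-0.09, SE 0.37), the beta myosin heavy chain gene Myh7 (0.04, SE 0.75) and skeletal actin Acta1 (-0.75, SE 0.56) did not pass. Nor did Ankrd1 (-0.03, SE 0.19), Atp2a2 (-0.28, SE 0.20), Pln (0.26, SE 0.17), Ryr2 (-0.33, SE 0.21), Casq2 (-0.03, SE 0.15), Col1a1 (0.22, SE 0.27), Col3a1 (0.49, SE 0.26), Postn (0.65, SE 0.30) or Ctgf (0.12, SE 0.29).

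No gene passed edgeR's quasi-likelihood test for the MYBPC3 deletion against nontransgenic hearts (smallest adjusted p 0.184), while 1130 genes had an unadjusted p under 0.05, 407 higher and 723 lower, against 692 by chance. DESeq2 called 89 genes (9 higher, 80 lower), the edgeR likelihood ratio test 15 and limma-voom 0. Of the deposited KEGG and GO terms, 28 of 3719 passed camera and 0 did with an estimated correlation (smallest adjusted p 0.992). Long transcripts were lower than short ones in this comparison, with a rank correlation across genes of -0.24 between log2 fold change and length. With the length trend removed 14 terms passed, and ribosomal proteins (median 0.00, adjusted p = 0.955) and interferon (0.12, 0.0945) were no longer called. In females alone, with 1 library in each of these 2 groups, the calls of hypoxia and angiogenesis (median -0.12, 0.106), heat shock (-0.13, 0.118), endothelial markers (-0.04, 0.566), extracellular matrix (0.08, 0.566) and ribosomal proteins (-0.10, 0.11) ended, and without the sex term those of antigen presentation (0.29, 0.0606) and interferon (0.12, 0.0606). Interferon was also not called with only the groups compared (0.14, 0.0807), with either other filter on low counts (0.0584 and 0.0556) or without HRC variant replicates 2 and 3 together (0.14, 0.0668). Without nontransgenic replicate 1 and MYBPC3 deletion replicate 2 together antigen presentation (0.26, 0.0945), the cell cycle (0.13, 0.0562), matrix (0.10, 0.183), heat shock (0.03, 0.35), ribosomal proteins (0.08, 0.063) and the sarcomere (-0.08, 0.108) were not called. Leaving out nontransgenic replicate 1 ended the calls of glycolysis (median -0.08, adjusted p = 0.129), the sarcomere (-0.13, 0.144), heat shock (0.00, 0.649) and endothelial markers (0.02, 0.468). The endothelial call ended without MYBPC3 deletion replicate 1 (0.02, 0.82), and without its replicate 2 those of heat shock (-0.16, 0.0558), extracellular matrix (0.10, 0.137), antigen presentation (0.12, 0.583), ribosomal proteins (-0.05, 0.783) and the interferon response (0.06, 0.352). Without MYBPC3 deletion replicate 3, or nontransgenic replicate 3, the only females of these groups, this contrast rests on the same males. Macrophages (0.16, 0.548 and 0.544), antigen presentation (0.22, 0.387 and 0.388) and interferon (-0.08, 0.548 and 0.544) lost their calls there. Without nontransgenic replicate 2 antigen presentation (0.41, 0.0868), ribosomal proteins (-0.05, 0.381) and interferon (0.14, 0.107) were not called, and interferon was not called without HRC variant replicate 1 (0.15, 0.0667) or 2 (0.15, 0.0535).

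The next comparison asked how hearts heterozygous for the HRC variant differ from nontransgenic hearts. Genes of the circadian clock fell as a list, with a median of -0.55 (quartiles -0.95 and 0.20), and 14 of 21 members were lower. The list's adjusted p was 4.83e-06, but 0.315 with an estimated correlation, and without the sex term the median was -0.28 (0.0137). Arntl, the core activator of the clock, had 3.37 ± 1.47 CPM (SD, n = 3) in nontransgenic hearts and 15.8 ± 6.67 with the HRC variant, a fitted log2 difference of 3.32 (SE 0.59). Without the sex term it was 2.24. The sex term rests on nontransgenic and MYBPC3 deletion mice, with 1 female in each group. Its partner Npas2 gave 1.52 (SE 0.39), the repressor Cry2 -0.55 (SE 0.13) and the clock output factor Tef -1.08 (SE 0.26). No clock gene passed edgeR over all genes, DESeq2 called 3 (Arntl, Cry2 and Tef), and 11 passed adjusted over the list alone: Arntl, Npas2, Per1, Per2, Per3, Cry2, Nr1d2, Tef, Hlf, Bhlhe41 and Usp2. Arntl (gene 11865) lies on GRCm38.p6 chromosome 7 from 113178470 to 113314126.

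**Figure D2:**
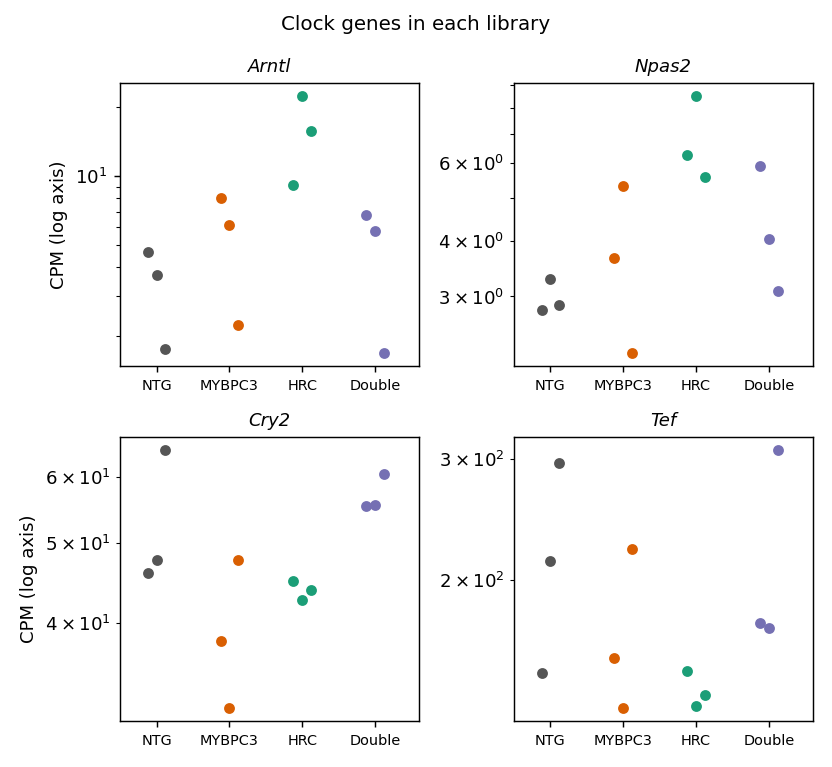
CPM (log axis) of 4 clock genes in each library, by group, with points as libraries. Arntl lay at 9.15, 22.5 and 15.8 CPM in the HRC variant libraries and between 1.75 and 4.65 CPM in nontransgenic libraries.

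Antigen presentation rose with the HRC variant by a median of 1.05 (quartiles 0.79 and 1.40), with 18 of 19 members higher, and the interferon response by 0.43, with 29 of 34 higher. These 2 lists had an adjusted p of 6.97e-14 and 1.34e-06, but 0.835 and 0.986 with an estimated correlation. Without the sex term the medians were 0.30 and 0.27. Relative to the mean of all libraries antigen presentation lay at 0.23, 0.09 and -0.99 in the nontransgenic libraries, the last of them the only female, and at 0.67, 0.00 and 0.04 with the HRC variant. H2-Q7, a class I histocompatibility gene with close copies, gave 2.75 (SE 0.78; 1.26 without the sex term), Nlrc5, an activator of class I genes, 2.01 (SE 0.64; 1.48 without), H2-Aa, a class II gene, 1.58 (SE 0.57; 0.42 without), and Oas2, an interferon-induced sensor of viral RNA, 0.90 (SE 0.26). In each of these lists 0 members passed edgeR over all genes and 0 adjusted over the list alone, while DESeq2 called H2-Q7. The cell cycle list also rose (median 0.55, or 0.11 without the sex term, 22 of 30 higher, adjusted p = 0.00013), as did nuclear genes of oxidative phosphorylation (0.13, 50 of 55, adjusted p = 0.0129), immediate early genes (0.21, 23 of 28, adjusted p = 0.016) and B-cell markers (1.08, 9 of 10, adjusted p = 0.0382), all 4 at 0.986 with an estimated correlation. Atrial muscle markers (-0.41, 19 of 19 lower, adjusted p = 0.000481), growth factors (-0.22, 21 of 29, adjusted p = 0.0106) and ion channels (-0.18, 22 of 30, adjusted p = 0.025) fell. With an estimated correlation the adjusted p was 0.835 for growth factors and ion channels and 0.986 for atrial markers, and 0 members of any of these 7 lists passed edgeR or DESeq2 over all genes or adjusted over the list alone. Nppb, a natriuretic peptide gene, gave 1.44 (SE 0.46; 0.57 without the sex term) and Ankrd1, a stretch-responsive muscle gene, 0.52 (SE 0.23; -0.22 without), and neither passed. The other markers did not pass either: Nppa (-0.88, SE 1.17), Myh7 (-0.37, SE 0.74), Myh6 (-0.26, SE 0.18), Acta1 (-0.97, SE 0.60), Atp2a2 (-0.35, SE 0.25), Pln (0.09, SE 0.21), Ryr2 (-0.31, SE 0.25), Casq2 (-0.14, SE 0.19), Col1a1 (0.06, SE 0.33), Col3a1 (0.44, SE 0.33), Postn (0.13, SE 0.36) and Ctgf (0.09, SE 0.33).

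No gene passed edgeR's test for the HRC variant against nontransgenic hearts (smallest adjusted p 0.224). An unadjusted p under 0.05 was found for 863 genes, 455 higher and 408 lower, against 692 by chance. DESeq2 called 24 genes (10 higher, 14 lower), the edgeR likelihood ratio test 10 and limma-voom 0. The 5 genes with the smallest p were Herpud1, of endoplasmic reticulum protein quality control (-1.02, SE 0.17), Bend6, a BEN-domain protein gene (gene 320705; GRCm38.p6 chromosome 1, 33852052 to 33908141; 2.86, SE 0.50), the predicted gene Gm3558 (5.09, SE 0.90), Dgat2, which makes triglycerides (-1.17, SE 0.21), and the metalloprotease gene Adam19 (1.35, SE 0.24). Of the terms, 16 of 3719 passed camera and 0 did with an estimated correlation (smallest adjusted p 1). Since all HRC variant mice were female, the sex term carries part of this comparison, and without it oxidative phosphorylation passed in the other direction (median -0.16, adjusted p = 0.00168), while immediate early genes (-0.18, 0.577) and B-cell markers (-1.17, 0.211) lost their calls with the median turned, and growth factors (-0.06, 0.609) and ion channels (0.00, 0.831) lost theirs as well. The rank correlation with transcript length was -0.21, and with that trend removed oxidative phosphorylation (0.01, 0.825), ion channels (-0.15, 0.101) and B-cell markers (1.05, 0.072) were not called. Adding the atrial level to the model ended the call of oxidative phosphorylation (0.07, 0.301). In females alone, with 1 nontransgenic library, ion channels had a median of -0.13. With only the 2 groups in the fit, again against that female, oxidative phosphorylation had 0.11, ion channels -0.13 and B-cell markers 0.69. Without HRC variant replicates 2 and 3 together growth factors (-0.20, 0.129), oxidative phosphorylation (0.18, 0.0766) and atrial markers (0.21, 0.28) lost their calls, and B-cell markers did so without nontransgenic replicate 1 and MYBPC3 deletion replicate 2 together (0.13, 0.715). Leaving out HRC variant replicate 1 raised the number of called genes from 0 to 8, and leaving out compound replicate 3 to 1. Atrial markers were no longer called without HRC variant replicate 3 (median -0.13, adjusted p = 0.344), and interferon (0.08, 0.773), cell cycle (0.20, 0.467) and growth factors (-0.23, 0.0644) without nontransgenic replicate 3. Oxidative phosphorylation lost its call without nontransgenic replicate 2 (0.04, 0.612), MYBPC3 deletion replicate 2 (0.06, 0.28) or 3 (0.10, 0.0931), or HRC variant replicate 3 (0.05, 0.344). Immediate early genes lost theirs without nontransgenic replicate 2 (0.10, 0.208), MYBPC3 deletion replicate 1 (0.20, 0.108) or 3 (0.23, 0.0981), or HRC variant replicate 1 (0.08, 0.277). Ion channels did so without nontransgenic replicate 2 (-0.16, 0.0532), MYBPC3 deletion replicate 2 (-0.14, 0.0567) or 3 (-0.14, 0.13), or HRC variant replicate 1 (-0.10, 0.0864). B-cell markers did so without nontransgenic replicate 1 (0.79, 0.243), MYBPC3 deletion replicate 2 (0.36, 0.471) or 3 (0.97, 0.161), or HRC variant replicate 1 (0.87, 0.254) or 2 (0.98, 0.0505).

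The comparison of compound hearts with nontransgenic hearts asked what both alterations do together. Markers of atrial muscle fell, with a median of -2.72 (quartiles -4.69 and -1.35) and 19 of 19 members lower. The list's adjusted p was 8.13e-27, but 0.593 with an estimated correlation. Nppa, the atrial natriuretic peptide gene (gene 230899; GRCm38.p6 chromosome 4, 148000722 to 148002074), had 3500 ± 1430 CPM (SD, n = 3) in nontransgenic hearts and 165 ± 78.3 in compound hearts, a fitted log2 difference of -4.52 (SE 1.21; adjusted p = 0.63, DESeq2 adjusted p = 0.00894). Gja5, a gap junction gene of atrium and conduction system, gave -2.20 (SE 0.54), Nr2f1, a transcription factor of atrial identity, -1.26 (SE 0.34), and Pam, which amidates peptides in atrial granules, -1.80 (SE 0.51). The atrial light chain genes Myl7 and Myl4 and the atrial calcium pump regulator Sln, chosen after their values were seen, had 22.5 ± 32.2, 32.7 ± 41.3 and 9.41 ± 14.1 CPM in compound hearts. In nontransgenic hearts they had 717 ± 365, 1120 ± 549 and 281 ± 144 CPM. No member passed edgeR over all genes, DESeq2 called Nppa and Sbk3, and 15 passed adjusted over the list alone. The mean of the list lay between 3.22 and 4.43 log2 CPM in the compound libraries and between 6.10 and 7.70 in nontransgenic libraries, and it was 3.24 in HRC variant replicate 3 against 7.59 and 6.41 in replicates 1 and 2.

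**Figure D3:**
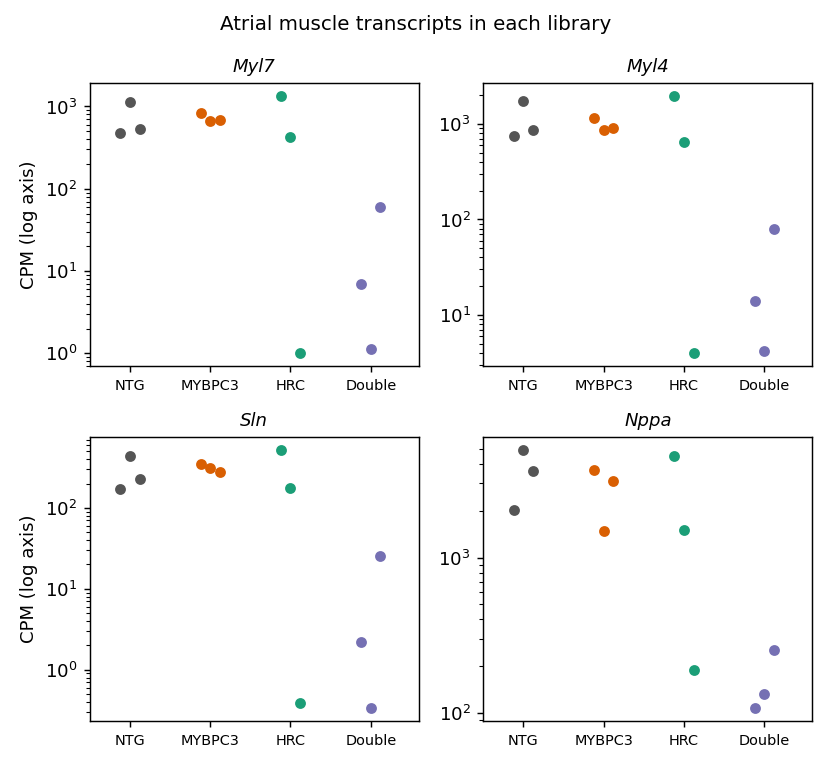
CPM (log axis) of 4 atrial muscle transcripts in each library, by group, with points as libraries. Nppa lay at 108, 133 and 254 CPM in compound libraries and at 190 CPM in HRC variant replicate 3, below the 1470 to 4890 CPM of the remaining libraries.

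Extracellular matrix genes fell in compound against nontransgenic hearts, with a median of -0.46 and 42 of 46 members lower, among them the matrix glycoprotein genes Fbln2 (-0.69, SE 0.20), Fbln1 (-0.96, SE 0.32) and Fn1 (-0.65, SE 0.25). The matrix list had an adjusted p of 1.63e-08, but 0.593 with an estimated correlation, and with the atrial level in the model the median was 0.04 (0.798). Fibroblast markers (median -0.35, 16 of 18 lower, adjusted p = 3.04e-05) and markers of epicardium (-0.85, 12 of 13, adjusted p = 0.00016) fell as well, and so did growth factors (-0.24, 21 of 29, adjusted p = 0.00339), skeletal muscle markers (-0.96, 7 of 10, adjusted p = 0.00578) and markers of Schwann cells and neurons (-0.48, 11 of 13, adjusted p = 0.00579). All 5 of these lists had 0.593 with an estimated correlation. Igf2, an insulin-like growth factor gene, gave -1.08 (SE 0.27), Casq1, the calcium store protein of skeletal muscle, -2.12 (SE 0.54), and Krt19, a mesothelial keratin, -1.35 (SE 0.59). Fatty acid oxidation rose by a median of 0.25, with 32 of 36 members higher, and oxidative phosphorylation by 0.19, with 54 of 55 higher. The adjusted p was 3.32e-06 and 8.94e-06, but 0.593 and 0.795 with an estimated correlation. Ucp3, a mitochondrial carrier induced by fatty acids, had 103 ± 40.5 CPM in compound and 52.6 ± 7.59 CPM in nontransgenic hearts (log2 difference 1.33, SE 0.40; 0.97 without the sex term). Antigen presentation (0.83, 17 of 19 higher, adjusted p = 2e-07), the interferon response (0.40, 29 of 34, adjusted p = 4.54e-06) and the cell cycle (0.34, 21 of 30, adjusted p = 0.0123) rose. With an estimated correlation the last was at 0.782 and the other 2 at 0.593. Over all genes 0 members passed edgeR, while DESeq2 called Igf2, Fgf16 and H2-Q7, and adjusted over the list alone 3 growth factors (Igf2, Igfbp3 and Fgf16), 1 skeletal muscle gene (Casq1) and 0 in the remaining 9 lists. Low values of several of these lists were not particular to compound hearts. Relative to the mean of all libraries the matrix list lay at -0.20, -0.49 and -0.54 in the compound libraries. HRC variant replicate 3, which by its label has no MYBPC3 deletion, lay at -0.53, against 0.76 and -0.06 in replicates 1 and 2. In that library epicardium lay at -1.16 and Schwann cells at -0.73.

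No gene passed edgeR's test between compound and nontransgenic hearts (smallest adjusted p 0.16). An unadjusted p under 0.05 was found for 881 genes, 296 higher and 585 lower, against 692 by chance. DESeq2 called 38 genes (12 higher, 26 lower), the edgeR likelihood ratio test 42 and limma-voom 0. The 5 genes with the smallest p were Fkbp5, a glucocorticoid-induced co-chaperone (gene 14229; GRCm38.p6 chromosome 17, 28398753 to 28486149; -1.56, SE 0.25), the nucleobase transporter gene Slc43a3 (-0.91, SE 0.15), Arrdc2, an arrestin family gene (-1.72, SE 0.28), the kinase gene Map3k6 (-1.43, SE 0.24) and Csdc2, a cold shock domain gene (-1.04, SE 0.18). Markers of ventricular stress did not pass: Nppb gave 0.16 (SE 0.44; -0.71 without the sex term), Myh7 -0.24 (SE 0.74), Myh6 -0.15 (SE 0.18), Acta1 -1.47 (SE 0.60) and Ankrd1 0.27 (SE 0.22; -0.48 without). Calcium cycling genes gave -0.11 (SE 0.25) for Atp2a2, 0.43 (SE 0.21) for Pln, -0.16 (SE 0.25) for Ryr2 and 0.04 (SE 0.19) for Casq2, and matrix genes -0.53 (SE 0.33) for Col1a1, 0.04 (SE 0.33) for Col3a1, -0.62 (SE 0.36) for Postn and -0.51 (SE 0.33) for Ctgf. Of the terms, 43 of 3719 passed camera and 0 did with an estimated correlation (smallest adjusted p 0.965). With the atrial level in the model the median was -0.09 for fibroblasts (adjusted p = 0.419), 0.36 for epicardium (0.107), 0.03 for fatty acid oxidation (0.95), 0.04 for oxidative phosphorylation (0.63), -0.08 for growth factors (0.107), -0.27 for skeletal muscle (0.131) and -0.04 for Schwann cells (0.93). The atrial list kept its call there (-0.69, 2.16e-08) and against the MYBPC3 deletion (-0.39, 2.39e-05) and the HRC variant (-0.50, 0.00014), but 3 of its members form that level. Its slope leans on HRC variant replicate 3 in all such fits. Without nontransgenic replicate 3 the calls of interferon (0.02, 0.822), skeletal muscle (-0.04, 0.373), Schwann cells (-0.21, 0.263) and the cell cycle (-0.08, 0.947) ended, the last also without nontransgenic replicate 1 (0.27, 0.0789) or MYBPC3 deletion replicate 2 (0.24, 0.10), and without both of these (0.18, 0.251). The number of called genes was 1 without nontransgenic replicate 1, 3 without HRC variant replicate 3 and 37 without HRC variant replicates 2 and 3 together. Without the sex term oxidative phosphorylation (median -0.13, 0.335), antigen presentation (0.00, 0.492), the cell cycle (-0.01, 0.468) and growth factors (-0.08, 0.461) were not called, and medians moved to 0.16 for fatty acid oxidation and -0.77 for Schwann cells.

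Compound hearts were compared with hearts that carry the MYBPC3 deletion alone, a comparison in which the HRC variant, sex and atrial markers differ together. Atrial markers fell, with a median of -2.11 and 19 of 19 lower, among them Sbk3, a kinase gene of heart muscle (-3.85, SE 0.99), and Nppa (-4.16, SE 1.19). The adjusted p was 8.09e-24, but 0.564 with an estimated correlation. Extracellular matrix fell, with a median of -0.68 and 44 of 46 lower, among them Postn, a matrix protein of activated fibroblasts, with 88.9 ± 18.7 CPM (SD, n = 3) in MYBPC3 deletion hearts and 39.2 ± 2.33 in compound hearts (log2 difference -1.27, SE 0.37). The matrix list had an adjusted p of 2.98e-18, but 0.564 with an estimated correlation. Fatty acid oxidation rose by 0.28, with 36 of 36 members higher, and the sarcomere by 0.19, with 23 of 30 higher, among them Myom2, an M-band protein gene (0.83, SE 0.20), and Myh6 (0.38, SE 0.18). Their adjusted p was 9.46e-09 and 0.000529, but 0.564 for both with an estimated correlation. The citric acid cycle (median 0.19, 20 of 20 higher, adjusted p = 0.000245), glycolysis (0.18, 27 of 30, adjusted p = 0.00108), antigen presentation (0.42, 17 of 19, adjusted p = 0.00172), oxidative phosphorylation (0.13, 51 of 55, adjusted p = 0.00172) and interferon (0.25, 26 of 34, adjusted p = 0.00662) rose, with 0.654, 0.654, 0.786, 0.866 and 0.831 by an estimated correlation. Markers of fibroblasts (-0.50, 16 of 18 lower, adjusted p = 2.04e-06), Schwann cells (-0.54, 13 of 13, adjusted p = 6.05e-05), epicardium (-0.71, 10 of 13, adjusted p = 0.000119), macrophages (-0.32, 18 of 22, adjusted p = 0.000529), skeletal muscle (-0.71, 8 of 10, adjusted p = 0.0192) and lymphatic vessels (-0.41, 5 of 7, adjusted p = 0.0304) fell, as did cytokines (-0.11, 15 of 26, adjusted p = 0.00468). With an estimated correlation these 7 lists had 0.564, except epicardium (0.569), macrophages (0.662) and cytokines (0.579). Over all genes 0 members passed edgeR, while DESeq2 called Myom2 and Nppa, and adjusted over the list alone 1 in the sarcomere (Myom2), 1 in lymphatic markers (Lyve1) and 0 in the other 14 of the 16 lists.

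No gene passed edgeR's test between compound and MYBPC3 deletion hearts (smallest adjusted p 0.548). An unadjusted p under 0.05 was found for 794 genes, 324 higher and 470 lower, against 692 by chance. DESeq2 called 11 genes (4 higher, 7 lower), the edgeR likelihood ratio test 4 and limma-voom 0, and DESeq2 without the sex term 221. The 5 genes with the smallest p were Cdh23, a cadherin gene (gene 22295; GRCm38.p6 chromosome 10, 60302748 to 60696513; 1.34, SE 0.22), Slc43a3 (-0.76, SE 0.15), the clone gene 9030025P20Rik (2.41, SE 0.48), Aspn, a matrix proteoglycan gene (-0.76, SE 0.16), and Ddit4, a stress-induced inhibitor of mTOR (-1.16, SE 0.25). Of the terms, 83 of 3719 passed camera and 0 did with an estimated correlation (smallest adjusted p 0.968). With the atrial level in the model 6 lists passed, and the calls of fatty acid oxidation (median 0.07, adjusted p = 0.525), the sarcomere (0.09, 0.17), glycolysis (0.07, 0.734), the citric acid cycle (-0.01, 0.961), fibroblasts (-0.10, 0.207), Schwann cells (-0.13, 0.39), epicardium (0.35, 0.0612), macrophages (0.02, 0.635), skeletal muscle (-0.14, 0.256), lymphatic vessels (0.03, 0.212), cytokines (-0.04, 0.17), interferon (0.21, 0.126) and oxidative phosphorylation (-0.02, 0.593) ended. Without MYBPC3 deletion replicate 3 macrophages (0.10, 0.908), cytokines (-0.01, 0.385) and oxidative phosphorylation (0.09, 0.207) were not called. Without nontransgenic replicate 3 antigen presentation (0.32, 0.0622), interferon (0.01, 0.924), skeletal muscle (-0.26, 0.12) and lymphatic vessels (-0.22, 0.41) were not. Antigen presentation (0.03, 0.872), interferon (0.03, 0.798) and oxidative phosphorylation (0.10, 0.0672) lost their calls without compound replicate 2. Oxidative phosphorylation (0.04, 0.202), interferon (0.28, 0.0633) and lymphatic vessels (-0.39, 0.0725) did so without nontransgenic replicate 1, and likewise without MYBPC3 deletion replicate 1 (0.08, 0.0719; 0.17, 0.146; -0.37, 0.0846). Lymphatic vessels also did so without compound replicate 3 (-0.42, 0.0587). Without HRC variant replicates 2 and 3 together 17 genes were called. Without the sex term the calls of antigen presentation (median -0.24, 0.403), oxidative phosphorylation (-0.22, 0.0513), interferon (0.07, 0.368) and lymphatic vessels (-0.28, 0.423) ended, and medians moved to 0.11 for the sarcomere, -0.41 for cytokines and -0.57 for macrophages. In females alone the medians of interferon and lymphatic vessels were 0.00 and -0.24, against 1 MYBPC3 deletion library. With only the 2 groups in the fit, again against that female, they were 0.01 and -0.23, antigen presentation had 0.31 and skeletal muscle -0.32. Skeletal muscle was not called without a filter on low counts (-0.70, 0.0581), and lymphatic vessels not without nontransgenic replicate 1 and MYBPC3 deletion replicate 2 together (-0.35, 0.0909).

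Compound hearts were compared with HRC variant hearts, in 6 female mice. Besides the MYBPC3 deletion, atrial markers also differed, except in HRC variant replicate 3. Atrial markers fell, with a median of -1.96 and 19 of 19 lower, and matrix genes fell, with a median of -0.50 and 44 of 46 lower. Their adjusted p was 6.93e-15 and 8.53e-13, but 0.50 and 0.648 with an estimated correlation. Eln, the elastin gene (gene 13717; GRCm38.p6 chromosome 5, 134702595 to 134747368), had 73.5 ± 21.9 CPM (SD, n = 3) with the HRC variant and 28.6 ± 9.89 in compound hearts (log2 difference -1.36, SE 0.29). Fatty acid oxidation rose by 0.24, with 34 of 36 higher, among them Ucp3 (1.38, SE 0.32) and Slc27a1, a fatty acid transporter gene (0.55, SE 0.14). That list had an adjusted p of 3.24e-09, but 0.648 with an estimated correlation. The clock list rose by 0.27, with 15 of 21 higher (adjusted p = 0.000568, but 0.50 with an estimated correlation), while Arntl gave -1.74 (SE 0.43). The call of the clock list ended without HRC variant replicates 2 and 3 together (median 0.02, adjusted p = 0.318). Fetal and hypertrophy genes fell (median -0.26, 23 of 27 lower, adjusted p = 0.00044), among them Nppa (-3.64, SE 1.07), Nppb (-1.28, SE 0.37) and Meox1, a regulator of fibroblast activation (-1.01, SE 0.27), with 0.50 for the list by an estimated correlation. Fibroblast (-0.43, 16 of 18, adjusted p = 1.16e-05), epicardium (-0.79, 12 of 13, adjusted p = 0.000386), Schwann cell (-0.41, 13 of 13, adjusted p = 0.00044) and skeletal muscle markers (-0.47, 7 of 10, adjusted p = 0.00963) fell, at 0.50 for skeletal muscle and 0.648 for the other 3 by an estimated correlation. Antigen presentation (-0.31, 18 of 19, adjusted p = 0.00963), heat shock (-0.16, 16 of 21, adjusted p = 0.00963) and cytokines (-0.22, 20 of 26, adjusted p = 0.0236) fell, and the citric acid cycle rose (0.12, 20 of 20, adjusted p = 0.00175). With an estimated correlation these 4 had 0.88, 0.828, 0.752 and 0.79. Over all genes 0 members passed edgeR, while DESeq2 called Nppa, Sbk3, Gja5, Eln, Ucp3, Slc27a1, Arntl and Casq1, and adjusted over the list alone 5 atrial, 5 clock, 2 fatty acid oxidation, 2 skeletal muscle and 1 matrix gene, with 0 in the other 8 of the 13 lists.

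No gene passed edgeR's test between compound and HRC variant hearts (smallest adjusted p 0.116). An unadjusted p under 0.05 was found for 872 genes, 330 higher and 542 lower, against 692 by chance. DESeq2 called 47 genes (21 higher, 26 lower), the edgeR likelihood ratio test 33 and limma-voom 0. The 5 genes with the smallest p were Bend6 (-2.74, SE 0.39), Dgat2 (1.07, SE 0.18), the predicted gene LOC100044068 (-6.79, SE 1.14), Klhl33, a kelch family gene (0.80, SE 0.14), and Shmt1, of one-carbon metabolism (1.21, SE 0.23). Of the terms, 37 of 3719 passed camera and 0 did with an estimated correlation (smallest adjusted p 0.998). Without HRC variant replicate 1, 5 lists were called in place of 13, and those of matrix (median -0.11, adjusted p = 0.093), fibroblasts (-0.08, 0.326), epicardium (-0.29, 0.556), Schwann cells (-0.17, 0.326), skeletal muscle (-0.26, 0.24), the citric acid cycle (0.05, 0.571), antigen presentation (-0.03, 0.805) and cytokines (-0.09, 0.959) ended. Heat shock was not called without HRC variant replicate 3 (-0.12, 0.609), compound replicate 1 (-0.14, 0.0617) or HRC variant replicates 2 and 3 together (0.03, 0.513), antigen presentation not without compound replicate 1 (-0.08, 0.61) or 3 (-0.18, 0.255), and cytokines not without compound replicate 3 (-0.15, 0.197) or with only the 2 groups in the fit (-0.21, 0.0642). Skeletal muscle was not called without a filter on low counts (-0.46, 0.0689). With the atrial level in the model 7 lists passed, and fibroblasts (median -0.17, adjusted p = 0.0753), epicardium (-0.01, 0.728), Schwann cells (-0.19, 0.257), skeletal muscle (-0.13, 0.112), cytokines (-0.12, 0.28) and the citric acid cycle (0.04, 0.641) did not. The number of called genes was 4 without HRC variant replicate 1, 13 without HRC variant replicate 3 and 308 without HRC variant replicates 2 and 3 together, where a lone library is assumed to vary like the other groups.

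The interaction asked whether the compound difference departs from the sum of the single differences, the question the series title raises. The extracellular matrix list lay below that sum, with a median difference of -0.64 and 42 of 46 members lower, as did cell cycle genes (-0.65, 27 of 30 lower) and atrial markers (-1.84, 18 of 19 lower). None of these 3 passed with an estimated correlation (adjusted p = 0.603 each). Fatty acid oxidation (0.31, 35 of 36 higher) and the sarcomere (0.20, 25 of 30 higher) lay above it, with an adjusted p of 0.624 and 0.603 with an estimated correlation. Eln gave -2.10 (SE 0.41), Postn -1.40 (SE 0.43) and Ccnb2 -3.26 (SE 0.74), while Myom2 gave 0.74 (SE 0.22), Myh6 0.64 (SE 0.21) and Mybpc3 itself 0.75 (SE 0.23; DESeq2 adjusted p = 0.0486). Among clock genes Arntl gave -2.38 (SE 0.62) and Cry2 0.81 (SE 0.15). The 5 genes with the smallest p were Bend6 (-3.73, SE 0.55), Shmt1 (2.00, SE 0.32), Xdh (1.03, SE 0.18), Cry2 and Ephb3, an ephrin receptor gene (1.14, SE 0.21).

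No gene passed edgeR's test of the interaction (smallest adjusted p 0.16). An unadjusted p under 0.05 was found for 1183 genes, 622 higher and 561 lower, against 692 by chance. DESeq2 called 51 genes (47 higher, 4 lower), the edgeR likelihood ratio test 14 and limma-voom 0. Of the 40 lists 18 passed camera, 6 above and 12 below the sum, and 0 passed with an estimated correlation (smallest adjusted p 0.603) or with fry. Adjusted over the list alone 1 matrix gene (Eln), 1 cell cycle gene (Ccnb2) and 3 clock genes (Arntl, Cry2 and Tef) passed, against 0 over all genes by edgeR and Eln, Cry2, Myom2, Myh6 and Mybpc3 by DESeq2. The adjusted p was 5.6e-11 for matrix, 1.92e-05 for the cell cycle, 6.09e-06 for atrial markers, 1.34e-05 for fatty acid oxidation and 0.000527 for the sarcomere. Of the terms, 85 of 3719 passed camera and 0 did with an estimated correlation (smallest adjusted p 0.997). With the atrial level in the model 8 lists passed. Without HRC variant replicate 1 the number of called lists was 9 and that of called genes 5, and without HRC variant replicates 2 and 3 together it was 189.

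**Figure D4:**
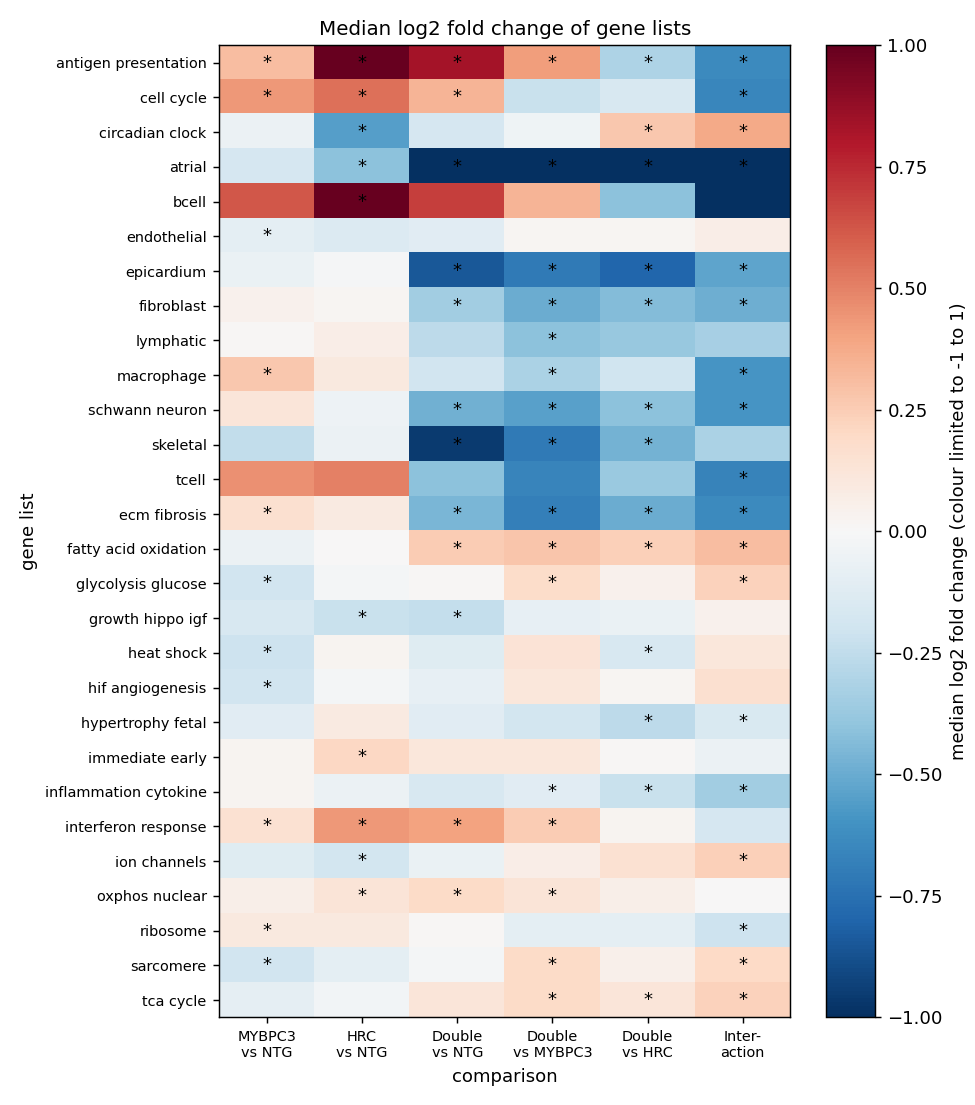
Median log2 fold change (colour, limited to the range from -1 to 1) of each of the 28 gene lists (vertical axis) that passed camera in at least 1 of the 6 contrasts (horizontal axis). A star marks an adjusted p under 0.05 at the preset correlation, and 0 lists passed with an estimated correlation. Atrial markers had medians of -2.72, -2.11 and -1.96 in the 3 contrasts of compound hearts with other groups.

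The authors' deposited table lists 407 genes at q under 0.05 between compound and nontransgenic hearts, 73 higher and 334 lower. Of these, 404 were tested here, 403 had the same sign in the same libraries and 247 an unadjusted edgeR p under 0.05. There the authors' fold changes of Nppb, Ankrd1, Atp2a2 and Ryr2 are those of DESeq2 without sex, not with it. Of the heart failure markers they call Nppa (log2 fold change -4.40, q = 8.77e-14), Acta1 (-1.63, 4.65e-09), Pln (0.54, 5.55e-05) and Col1a1 (-0.54, 0.0214). The others have a q of at least 0.0581. Against MYBPC3 deletion hearts the authors list 716 genes for compound hearts, 246 higher and 470 lower, with Mybpc3 at 0.51 (q = 0.00128). Against HRC variant hearts they list 65, 28 higher and 37 lower. Against nontransgenic hearts they list 16 for the MYBPC3 deletion and 13 for the HRC variant.

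Genes with a called sex difference were 8, of which Eif2s3y, Ddx3y, Kdm5d, Uty and Hsd11b1, an enzyme that reactivates glucocorticoids, were higher in males and Kdm6a, Eif2s3x and Kdm5c lower. An unadjusted p under 0.05 for sex was found for 1975 genes. With 0 called genes the overlap of calls against nontransgenic hearts was 0 for each pair of mutant groups. By DESeq2 it was 3 genes for the MYBPC3 deletion and the compound group, 8 for the HRC variant and the compound group, and 5 for the single mutants. Independent lists would share 0.191 lower genes in the first pair, 0.0254 lower and 0.00838 higher in the second, and 0.116 lower in the third. Across genes, which are not independent replicates, the log2 fold changes of the HRC variant and the compound group against the same nontransgenic libraries correlated at 0.70, and at 0.66 in 100 simulations of unchanged groups. Their covariance was 0.17 against 0.124 simulated. For the MYBPC3 deletion and the compound group the correlation was 0.36 (0.41 simulated) and the covariance 0.0742 (0.0624 simulated), and for the single mutants 0.47 (0.41) and 0.0827 (0.0626). The 3 control libraries are too few to be split, so part of each excess can come from the shared controls.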

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

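The tests of tissue content, sex, transcript length and time of day were chosen after the results they concern had been seen, while the splits of the samples and the test of the interaction were planned.

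The results below are lists of genes for which the compound group departed from the sum of the single mutants, by camera's test of the interaction. Each value is the median log2 departure, and no list passed with an estimated correlation, and each sentence gives the adjusted p with that correlation. Below the sum lay extracellular matrix at -0.64 (0.603), where the single mutants had medians of 0.16 and 0.09 against nontransgenic hearts and the compound group -0.46. Also below it lay antigen presentation at -0.64 (17 of 19 lower), the cell cycle at -0.65 and atrial markers at -1.84, with 0.661, 0.603 and 0.603. Lower too were fibroblasts at -0.49 (15 of 18), macrophages at -0.59 (19 of 22), T cells at -0.67 (7 of 8), Schwann cells and neurons at -0.59 (13 of 13) and epicardium at -0.53 (12 of 13), with 0.624, 0.667, 0.603, 0.603 and 0.673. Ribosomal proteins at -0.21 (35 of 37), cytokines at -0.35 (21 of 26) and hypertrophy genes at -0.15 (16 of 27) completed the lower lists, with 0.755, 0.659 and 0.603. Above the sum lay the sarcomere at 0.20, where the single mutants had -0.19 and -0.10 and the compound group -0.02, and fatty acid oxidation at 0.31, with 0.603 and 0.624. Glycolysis at 0.23 (26 of 30 higher), the citric acid cycle at 0.23 (20 of 20), the clock at 0.38 (15 of 21) and ion channels at 0.24 (21 of 30) were higher as well, with 0.624, 0.653, 0.603 and 0.603.

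At the preset correlation the adjusted p was 0.000527 for antigen presentation, 0.000859 for the citric acid cycle, 0.00142 for Schwann cells, 0.00153 for glycolysis, 0.00157 for fibroblasts, 0.00204 for macrophages and 0.0029 for the clock and for ribosomal proteins. It was 0.0198 for epicardium, 0.0359 for cytokines, 0.0438 for hypertrophy genes and 0.0442 for ion channels and T cells. Beside each lost call the median and the adjusted p are given. The atrial level in the model ended the calls of fibroblasts (median -0.22, 0.0986), macrophages (-0.37, 0.137), T cells (-0.70, 0.137), Schwann cells (-0.20, 0.137), epicardium (0.17, 0.641), cytokines (-0.28, 0.145), hypertrophy genes (-0.14, 0.186), glycolysis (0.17, 0.089) and the citric acid cycle (0.14, 0.0986). The same model leaves -0.12 (0.222) of the atrial list, which tests nothing, since that level is the mean of 3 of its members. With the length trend removed ribosomal proteins (-0.05, 0.564), hypertrophy genes (-0.15, 0.0961), ion channels (0.19, 0.123) and T cells (-0.61, 0.078) were not called. In females alone ribosomal proteins (0.01, 0.758), hypertrophy genes (0.10, 0.463) and ion channels (0.12, 0.341) were not, and without the sex term T cells (-0.61, 0.0681) and ion channels (0.24, 0.0652) were not. The clock (0.28, 0.215), T cells (-1.04, 0.155) and ion channels (0.34, 0.0727) lost their calls without HRC variant replicates 2 and 3 together. Epicardium (-0.55, 0.0731), Schwann cells (-0.22, 0.0731), T cells (-0.59, 0.345) and hypertrophy genes (-0.17, 0.11) did so without nontransgenic replicate 1 and MYBPC3 deletion replicate 2 together. T cells were not called without a filter on low counts (-0.67, 0.283), nor ion channels with a stricter one (0.24, 0.0566). Without HRC variant replicate 1 the calls of the citric acid cycle (0.15, 0.0685), fibroblasts (-0.18, 0.154), macrophages (-0.20, 0.482), Schwann cells (-0.23, 0.076), epicardium (-0.06, 0.503), cytokines (-0.20, 0.503), hypertrophy genes (-0.23, 0.137), ribosomal proteins (-0.07, 0.411), T cells (-0.70, 0.462) and ion channels (0.16, 0.0501) ended. Glycolysis was not called without nontransgenic replicate 1 (0.13, 0.0584). Ribosomal proteins were not called without nontransgenic replicate 2 (-0.03, 0.737) or MYBPC3 deletion replicate 2 (-0.05, 0.472), and hypertrophy genes not without the same libraries (-0.11, 0.235 and -0.15, 0.211) or without genes on X and Y (-0.11, 0.0668). Without nontransgenic or MYBPC3 deletion replicate 3 the effect of the deletion alone rests on the same males. There macrophages (-0.39, 0.147 and 0.148), cytokines (-0.14, 0.158 and 0.159), epicardium (-0.35, 0.0699 and 0.0664) and T cells (-0.36, 0.326 in both) were not called. Epicardium also lost its call without nontransgenic replicate 1 (-0.26, 0.128), HRC variant replicate 2 (-0.50, 0.0689) or compound replicate 2 (-0.36, 0.12), and cytokines without compound replicate 3 (-0.29, 0.10). T cells did so without nontransgenic replicate 1 (-0.59, 0.281), MYBPC3 deletion replicate 2 (-0.78, 0.267), HRC variant replicate 2 (-0.69, 0.128) or 3 (-0.56, 0.0712), or compound replicate 1 (-0.41, 0.156) or 3 (-0.65, 0.218). Ion channels did so without nontransgenic replicate 2 (0.10, 0.266), MYBPC3 deletion replicate 2 (0.18, 0.166), HRC variant replicate 2 (0.26, 0.0543) or 3 (0.26, 0.0837), or compound replicate 1 (0.25, 0.108) or 3 (0.20, 0.0617).

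Atrial muscle transcripts were low in all 3 compound libraries and in HRC variant replicate 3. Sex as the whole cause is argued against by a median male minus female difference of -0.17 within the groups that hold both sexes (quartile range 0.46), under the bound of 1.36 set for this test, where the compound median was -2.72, and the compound genotype cannot explain HRC variant replicate 3, which lay -3.75 from the mean of the other libraries of its group. Different amounts of atrial tissue in the samples may underlie the pattern: within groups, over the 9 libraries without the compound genotype, list members moved together with a median correlation of 0.85, against 0.20 at the upper end of random lists of the same size, and of 0.82 against 0.22 without HRC variant replicate 3, itself part of the pattern. The compound genotype stays open for the compound libraries, since the highest of them lay -1.67 from the lowest nontransgenic library and atrial content and genotype cannot be told apart there. Of the list's 19 members 8 are also in another list, and averaged over the 4 groups its most abundant were Nppa, Pam, Myl4 and Myl7 at 2114, 1414, 752 and 515 CPM, while in compound hearts Pam (624) lay above Nppa (165).

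Long transcripts were lower in MYBPC3 deletion than in nontransgenic libraries, with a rank correlation of -0.24 across genes, which are not independent replicates. A transcript length bias between libraries may be the source, since replicates of the same group differed by a rank correlation of up to 0.46. The MYBPC3 deletion cannot be told apart from it: compound against HRC variant libraries gave 0.13, and between -0.08 and 0.25 when each library was left out in turn.

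Clock genes were shifted in the HRC variant libraries. The HRC variant as the whole cause is argued against by its effect on the clock score, the mean log2 of activators less that of their targets: it was 2.68 (SE 0.62) against nontransgenic hearts and 0.71 (SE 0.62) when added to the MYBPC3 deletion, a difference of -1.97 (SE 0.72). An effect of the variant that the MYBPC3 deletion removes was not tested apart from this. The time of day at collection could also shift these genes; the score ranged over 1.59 among the 3 HRC variant libraries, under the bound of 2 set for this test, so the time of day and the group cannot be told apart.

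Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. Where the real split called 0 genes, every split reaches that count, so these counts of genes test nothing. The real split and the highest other gave 0 and 3 genes for the MYBPC3 deletion against nontransgenic hearts (10 of 10 splits reach 0), 0 and 120 for the HRC variant against nontransgenic hearts, and 0 and 0 for each of the 3 comparisons of the compound group. The 120-gene split set nontransgenic replicate 1 and HRC variant replicates 2 and 3 against the rest. These 3 had the lower atrial list means (6.10, 6.41 and 3.24 against 7.27 to 7.70). For lists the real and highest other values were 11 and 17 for the MYBPC3 deletion (8 splits with as many), 10 and 23 for the HRC variant (9), and 12 and 21 for the compound group against nontransgenic hearts (7). They were 16 and 16 for the compound group against the MYBPC3 deletion (2) and 13 and 17 against the HRC variant (5). For the interaction 100 splits were counted, the real one included: 14 gave at least the real 18 lists, with 22 the highest, so chance cannot be excluded for the lists. All 100 reach the real 0 genes, with 54 the highest, which by the same token tests nothing.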

How the results depend on the processing

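The models with the atrial level and with the length trend removed, those without pairs of libraries, the likelihood ratio test, the bias-adjusted test, DESeq2 without sex and all alternatives for the deposited terms were chosen after seeing the data. So were, for lists, leaving out libraries, the fit of only the groups compared, RLE scaling, the filters on low counts and leaving out genes on X and Y. Of the values of lists that passed, 1662 of 2061 kept camera's direction and their side of the threshold, 372 kept camera's direction and lost the call, and 27 turned in camera's direction. The median changed sign in 8 of the 372 and in 21 of the 27. A call lost at a similar median does not show a smaller change. Of the named genes' values 11228 kept both, 217 passed under an alternative and 73 turned. The pseudocounts planned for normalized values were not run, since the file holds counts. For the causes of the changes below, the cause was not tested except where fewer samples are named. Depth limits the analysis to 13849 genes, since 3530 had too few reads to be tested. The bias-adjusted quasi-likelihood test, limma-voom, RLE scaling, the filters on low counts and leaving out genes on X and Y also called 0 genes in all 6 contrasts, where edgeR found 1130, 863, 881, 794, 872 and 1183 genes at an unadjusted p under 0.05. So did edgeR without sex, in females alone, with the atrial level and with the length trend removed.

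In the order MYBPC3 deletion, HRC variant and compound group against nontransgenic hearts, compound group against MYBPC3 deletion and against HRC variant, and interaction, DESeq2 with sex called 89, 24, 38, 11, 47 and 51 genes, DESeq2 without sex 37, 23, 148, 221, 33 and 12, and the likelihood ratio test 15, 10, 42, 4, 33 and 14. DESeq2 with length factors called 61, 59, 53, 9, 66 and 37, of which 44, 22, 35, 7, 42 and 20 were also called without them. With only the groups compared, edgeR called 1 gene for the MYBPC3 deletion, 15 for the compound group against nontransgenic hearts and 57 against the MYBPC3 deletion. Without HRC variant replicates 2 and 3 together it called 1 for the HRC variant, 37 and 17 for the compound group against nontransgenic and MYBPC3 deletion hearts, 308 against the HRC variant and 189 for the interaction. The shared calls rose from 0 to 3, 8 and 5 with DESeq2 for the pairs of the MYBPC3 deletion and compound group, of the HRC variant and compound group, and of the single mutants.

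Estimated correlations and fry called 0 lists in every contrast, and estimated correlations 0 terms. With the atrial level in the model the compound group had 6 lists against the MYBPC3 deletion, 7 against the HRC variant and 8 in the interaction, and 2, 0, 2 and 16 terms against nontransgenic, MYBPC3 deletion and HRC variant hearts and in the interaction. Without HRC variant replicates 2 and 3 together 22 lists passed for the HRC variant. In females alone 35 terms passed for the compound group against the MYBPC3 deletion and 47 in the interaction. With the length trend removed 14 terms passed for the MYBPC3 deletion.

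With each library left out in turn, the genes called ranged from 0 to 8 for the HRC variant, 0 to 3 for the compound group against nontransgenic hearts, 0 to 13 against the HRC variant and 0 to 5 in the interaction. The lists called ranged from 6 (without MYBPC3 deletion replicate 2) to 14 for the MYBPC3 deletion, from 6 (without MYBPC3 deletion replicate 3) to 14 for the HRC variant and from 13 to 19 (without nontransgenic replicate 2) for the compound group against nontransgenic hearts. They ranged from 5 to 17 against the HRC variant and from 9 to 20 in the interaction, both lowest without HRC variant replicate 1. For the MYBPC3 deletion the ranges were -0.31 to 0.00 for heat shock, -0.08 to 0.37 for interferon, -0.05 to 0.22 for ribosomal proteins, -0.20 to 0.11 for Hrc and -0.23 to 0.53 for Ctgf. For the HRC variant they were 0.08 to 0.73 for interferon, -1.15 to 2.52 for Myh7, -1.53 to 0.65 for Acta1, -0.42 to 0.26 for Col1a1, -0.36 to 0.60 for Postn and -0.26 to 0.96 for Ctgf. For the compound group they were 0.02 to 0.75 for interferon, -1.01 to 2.66 for Myh7, -2.02 to 0.16 for Acta1 and -0.86 to 0.37 for Ctgf against nontransgenic hearts, and -0.50 to 0.10 for macrophages against the MYBPC3 deletion. The interferon medians of 0.02 and 0.08 count as turned because camera's test, not the median, changed direction. Without nontransgenic replicate 3 Myh7, Acta1 and Ctgf of the compound group turned.

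Without sex in the edgeR model these turned for the HRC variant: oxidative phosphorylation to -0.16, immediate early genes to -0.18, B cells to -1.17, Cox7a1 to -0.04, Atp5j to -0.02, Cox6c to -0.11, Cox7c to -0.08, Nr4a3 to -0.17, Atf3 to -0.20, Blk to -0.31, Ms4a1 to -2.18, Jchain to -2.71, Ankrd1 to -0.22, Atp2a2 to 0.06 and Ryr2 to 0.09. DESeq2 without sex gave Cox7a1 -0.05, Atp5j -0.03, Cox6c -0.11, Cox7c -0.09, Nr4a3 -0.18, Atf3 -0.21, Blk -0.33, Ms4a1 -2.18, Jchain -2.73, Ankrd1 -0.23, Atp2a2 0.06 and Ryr2 0.08. For the compound group against nontransgenic hearts edgeR without sex gave oxidative phosphorylation -0.13, Cox6c -0.01, Cox7c -0.01, H2-DMa -0.03, Cdk1 0.00, Nppb -0.71, Ankrd1 -0.48, Atp2a2 0.31 and Ryr2 0.23, and DESeq2 without sex gave Cox6c -0.01, Cox7c -0.01, H2-DMa -0.04, Cdk1 -0.01, Nppb -0.71, Ankrd1 -0.48, Atp2a2 0.31 and Ryr2 0.24. Against the MYBPC3 deletion edgeR without sex gave oxidative phosphorylation -0.22 and antigen presentation -0.24.

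In females alone, with 1 nontransgenic and 1 MYBPC3 deletion library assumed to vary like the other groups, ribosomal proteins turned to -0.10, Rpl41 to -0.02, Rpl32 to -0.01, Rps23 to -0.13, Myh7 to -2.52, Casq2 to 0.16 and Ctgf to -0.68 for the MYBPC3 deletion. For the HRC variant Ctgf turned to -0.26, and interferon for the compound group against the MYBPC3 deletion to 0.00. With only the groups compared, which rests on the same females, these were -0.26 and 0.01. In the interaction hypertrophy genes had 0.10 and ribosomal proteins 0.01 in females alone. With the atrial level in the model epicardium turned to 0.36, Pmp22 to 0.02, Krt8 to 0.10, Krt7 to 0.57 and Casq2 to -0.21 for the compound group against nontransgenic hearts. Against the MYBPC3 deletion oxidative phosphorylation turned to -0.02, epicardium to 0.35 and Atp2a1 to 0.09, against the HRC variant epicardium had -0.01 and Krt7 0.10, and epicardium had 0.17 in the interaction. Without nontransgenic replicate 1 and MYBPC3 deletion replicate 2 together heat shock had 0.03 and Hrc 0.17 for the MYBPC3 deletion. Without HRC variant replicates 2 and 3 together, where 1 library is assumed to vary like the other groups, atrial markers had 0.21, Hrc -0.23, Nr2f2 0.06 and Pln -0.36 for the HRC variant, and heat shock 0.03 and Chordc1 0.26 for the compound group against it.

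The replicate numbers do not pair the samples: of 18 pairs of libraries that share a number, 5 correlated above 0.1, with correlations from -0.24 to 0.316. With the replicate number as a replicate block edgeR called 1 gene in the interaction and 0 in the other contrasts. With the replicate block 34 terms passed for the HRC variant and 147 and 167 for the compound group against nontransgenic and MYBPC3 deletion hearts. With the replicate block Jchain turned to -1.35, Col1a1 to -0.41 and Col3a1 to -0.09 for the HRC variant, and Col3a1 to -0.53 for the compound group. The replicate block also ended the calls of antigen presentation (median 0.07, adjusted p = 0.342), interferon (0.06, 0.634) and lymphatic vessels (-0.62, 0.0569) for the compound group against the MYBPC3 deletion, and of the cell cycle (0.21, 0.129) against nontransgenic hearts. With the replicate block the calls of immediate early genes (0.06, 0.312), B cells (0.50, 0.39) and ion channels (-0.17, 0.0895) for the HRC variant, of interferon (0.12, 0.0568) for the MYBPC3 deletion and of hypertrophy genes (-0.15, 0.0508) in the interaction ended as well.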

Other observations

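Among the KEGG and GO terms of the deposited table, which were planned, collagen-containing extracellular matrix was lower in compound hearts against nontransgenic hearts (224 genes, median log2 fold change -0.24, camera adjusted p = 4.45e-06, but adjusted p = 0.965 with an estimated correlation). Acute-phase response, the liver-type reaction to inflammation, was lower there too (16 genes, median -0.52, adjusted p = 0.00204, with an estimated correlation 0.965). The mitochondrial matrix term was higher in compound against MYBPC3 deletion hearts (199 genes, median 0.17, adjusted p = 0.000331, with an estimated correlation 0.968), but with the atrial level in the model 0 terms passed there, against 2 for the compound group against nontransgenic hearts and 16 in the interaction. Lymphocyte chemotaxis lay below the sum of the single mutants (24 genes, median -0.78, adjusted p = 0.00183, with an estimated correlation 0.997). In MYBPC3 deletion hearts terms of vessel and muscle formation were lower, with medians of -0.31 for venous blood vessel morphogenesis (10 genes, adjusted p = 0.00257) and -0.23 for cardiac muscle tissue morphogenesis (20 genes, adjusted p = 0.00376), each with an adjusted p of 0.992 with an estimated correlation. In HRC variant hearts the KEGG term of antigen processing and presentation was higher (64 genes, median 0.37, adjusted p = 2.24e-07, with an estimated correlation 1).

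Of the 40 lists 12 passed in no contrast, and for each the smallest camera adjusted p over the 6 contrasts is given here. It was 0.489 for adrenergic and other receptors, 0.08 for apoptosis, 0.145 for autophagy, 0.437 for calcium handling, 0.308 for brown fat, 0.414 for erythroid cells, 0.478 for smooth muscle and pericytes, 0.249 for white fat, 0.0783 for endoplasmic reticulum stress, 0.292 for lipid synthesis, 0.348 for oxidative stress and 0.298 for sex-linked genes. Markers of lung (2 tested), neutrophils (4), thymus (3) and the genes of mitochondrial DNA (0) had too few tested members.

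The first principal component held 41.3% of the variance, with compound libraries at -27.1, -34.23 and -22.2, HRC variant replicate 3 at -41.06 and the remaining libraries between -10.09 and 37.76. The second held 13%. The authors' deposited table lists 48 genes at q under 0.05 between the MYBPC3 deletion and the HRC variant, a pair not compared here.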
